A study of Rattus norvegicus with 6 samples.

How the data were processed

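RNA from mammospheres of hCG-treated and control rats was measured on 6 Affymetrix 3' arrays, 3 per group, after a labelling with 2 rounds of amplification, per the labels' protocols. The values used were the authors' deposited table of log2 expression, with a row for each of 31099 probe sets and a column for each array. The submitters' processing notes name RMA, MAS5 and limma, with no versions and no roles. No source states the log base or normalization: from the values themselves, which ran from 0.74 to 13.1 with nearly the same distribution on each array, they were taken as log2 after normalization between arrays. Column medians were 3.45, 3.48 and 3.46 for Control 5, 6 and 7, and 3.44, 3.46 and 3.45 for hCG 5, 6 and 7. Such a normalization makes the arrays' distributions alike, so a change shared by most genes would not be seen. There were 0 missing values, and scanner files were not used here.

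Groups and array numbers came from the sample titles. The design text speaks of 3 animals per group, but nothing states that each array is a separate animal, so p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision, with 4 residual degrees of freedom. No labels name a batch, day or litter.

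The 57 Affymetrix control probe sets were left out of the tests, and used only as measures of RNA quality and spiked transcripts. The dimmest 40% of the other probe sets by their mean over all 6 arrays, below a log2 value of 2.67, were left out, which left 18625. Gene names came from the platform annotation. Of the 31042 probe sets, 20826 named 1 gene, 436 named several and 9780 named none; only the first kind was used for genes. Symbols of 20758 were updated through the Entrez gene number with a RefSeq gene table of the rat assembly GRCr8, used for names alone, and 68 kept their symbol. Each gene was represented by its brightest tested probe set, giving 10424 genes. Of 41 called genes with several probe sets, 4 had probe sets of opposite sign, Per2, Rassf1, Svil and Fli1.

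hCG was compared with control by lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, trend or robust setting, with a two-sided test and Benjamini-Hochberg adjustment over all tested probe sets, at adjusted p under 0.05. For genes, the adjustment was repeated over the 10424 chosen probe sets. Gene lists (45, with 886 distinct genes of which 645 were tested) were tested with camera of limma at a preset correlation of 0.01 where at least 5 genes were measured, which left 42, with Benjamini-Hochberg adjustment over lists. The level of a list on an array is the mean of its genes' log2 values, each relative to its control mean. Single measures per array were compared by exact two-sided permutation of the groups, which has 10 splits and a smallest p of 0.1.

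The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls among called genes with no overlap between groups. It adds the 4 members of smallest p in the direction of each list that passed, the 15 called list members of largest change, and 20 genes of mammary biology whatever their values. Other genes are named where a count of 5 or fewer is described or, in the closing part, as chosen after their values were seen. Alternatives were no filter or a 60% filter, median centring, quantile normalization or cyclic loess, the array number as a block, array weights, the mean of a gene's probe sets, each array left out, eBayes with trend or robust, and a minimum fold. For lists they were an estimated correlation, fry, and lists without shared genes. A threshold of adjusted p under 0.10 and the luminal minus basal difference were added after seeing the data. So were the spiked transcript measures and 5 further gene lists, which leave out the called genes that prompted them and serve only the closing part. Pseudocounts planned for linear values did not apply.

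The gene test was tried on simulated values for 18625 probe sets with 200 changed, with the means of the data and the spreads as moderated by eBayes. It recovered 187 at a log2 change of 1, with 10 false calls, and 198 at a change of 2, with 9 false calls. Moderated spreads differ less between probe sets than the raw ones, so recovery in the data may be lower. With 2 of 42 lists shifted by 0.5, camera recovered both, with 0 other calls. The simulated genes were independent, whereas the estimated correlation in the data was 0.70 for mitosis genes and 0.69 for endothelial markers. The simulation therefore cannot show how camera at the preset correlation behaves with correlated genes.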

Results

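Gene expression was measured on Affymetrix 3' arrays in mammospheres, floating spheres grown from single mammary cells kept off the culture surface. The cells came from female Sprague Dawley rats given recombinant human chorionic gonadotropin (hCG), the pregnancy hormone that acts on the ovary through the luteinizing hormone receptor, or buffer alone. Treatment began at 55 days of age, at 100 IU per day for 21 days. Glands were taken 21 days after the last dose, and epithelium-enriched cells were grown for 7 days before spheres were collected. The data held 3 control arrays and 3 hCG arrays, numbered 5, 6 and 7 in each group, with 31099 probe sets each. Array medians lay between 3.44 and 3.48 on the log2 scale. The comparison asked which genes differed in spheres formed after hCG exposure had ended.

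In spheres from hCG-treated rats the lists of endothelial and cell division genes were higher, and those of several immune, secretory and luminal genes lower, by limma's camera test with a preset correlation. Few members of these lists passed the gene test over all genes, and 0 lists passed with an estimated correlation (smallest adjusted p = 0.474). Among the named genes that passed the gene test, Abi3bp, an extracellular matrix protein, rose most, by a log2 change of 2.46 (SE 0.34, 5.52-fold). It was followed by Mest, an imprinted gene active in growing tissue, at 2.31 (SE 0.26, 4.97-fold). The largest fall was that of Dusp2, a phosphatase that switches off MAP kinases, with a log2 change of -2.90 (SE 0.46, 7.46-fold). The neuropeptide gene Npy changed by -2.89 (SE 0.46) and Cst7, a protease inhibitor of immune cells, by -2.57 (SE 0.36).

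The other large rises were those of Lrrc17 (2.18), the transcription factor Sox17 (2.15), the heparin-binding growth factor Ptn (2.09) and the septin gene Septin4 (2.07). Cd93, Emcn and Adgrl4, which encode surface proteins of endothelial cells, rose by 2.03, 1.89 and 1.84, and the fatty acid carrier Fabp4 by 1.91. The other large falls were those of Fbxo2 (-2.39), the inositol transporter Slc5a3 (-2.14), Lbp (-2.12), the sodium pump regulator Fxyd2 (-1.97), the granulocyte growth factor Csf3 (-1.69), the prostaglandin E synthase Ptges (-1.63) and the histone gene Hist4h4 (-1.59). SEs of these 20 log2 changes lay between 0.18 and 0.46, and in each gene the 3 hCG values lay outside the range of the 3 control values. Control means of Abi3bp (2.42) and Sox17 (2.23) and hCG means of Fbxo2 (2.12) and Ptges (1.89) lay below the filter level of 2.67. Their folds therefore start or end at dim signal. The ranking covers called genes only: Csn3 (-2.84) and Saa3 (-2.67), not called, changed by more than Cst7.

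**Figure D1:**
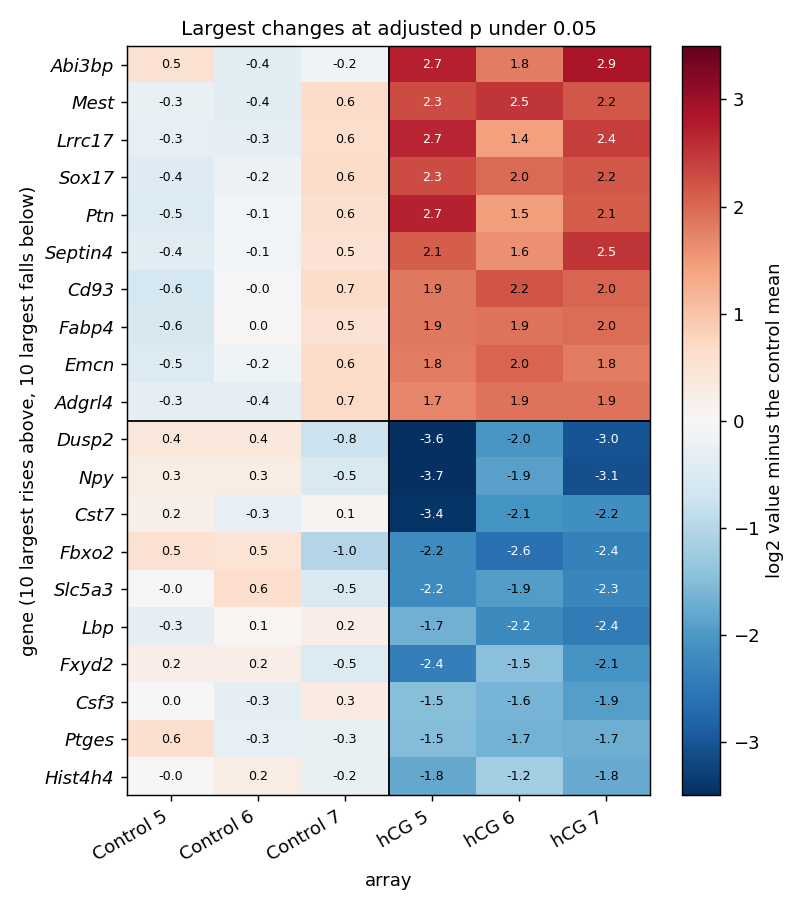
Heat map of the 10 largest rises and 10 largest falls at adjusted p under 0.05 (rows) on the 6 arrays (columns); colours and printed numbers give the log2 value minus the mean of the 3 control arrays. In each gene the 3 hCG arrays lie on one side of the 3 control arrays, with mean log2 values of 8.37 and 5.47 (control and hCG) for Dusp2 and 2.42 and 4.89 for Abi3bp.

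In all, 177 of 10424 genes passed limma's moderated test with Benjamini-Hochberg adjustment, 96 higher and 81 lower in hCG spheres (n = 3 arrays per group). Adjusted p of the named rises and falls lay between 0.0329 and 0.0474. Of the 177 genes, 33 were higher and 37 lower by at least 2-fold. The same test called 298 of 18625 probe sets, 151 higher and 147 lower. Groups did not overlap in 3295 genes (31.6%), where 10% would do so by chance. These gene calls rested on most of the arrays together: without Control 5, Control 6, hCG 5 or hCG 7 limma called 0 genes, with 1950, 1931, 1649 and 1455 genes at an unadjusted p under 0.05 against 2510 with all arrays. Without Control 7 it called 587 genes, 173 of them among the 177. Without hCG 6 it called 245, 112 of them among the 177, and 11 of the 36 called genes that the naming rule gave lost their call: Adgrl4, Cd93, Emcn, Esam, Fbxo2, Inhbb, Nqo1, Plau, Pola1, Prim1 and Ptges (adjusted p from 0.0511 to 0.0714). With 1 array left out in turn, the log2 change of Abi3bp lay between 2.26 and 2.80, that of Mest between 2.13 and 2.63, that of Cd24 between -1.52 and -1.26 and that of Dusp2 between -3.33 and -2.53. Array weights called 2540 genes, a variance trend 293, and the array number as a block 0.

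On average, arrays of one group resembled each other more than arrays of different groups. The mean Pearson correlation over tested probe sets was 0.988 within groups and 0.977 between them, and 1 of 10 splits of the arrays gave a difference as large (exact, two-sided p = 0.1, the smallest possible for 3 against 3). Single correlations overlapped: the lowest within a group was 0.980 and the highest between groups was 0.984. Control 7 correlated more with hCG 6 (0.9836) than with Control 6 (0.9829) or Control 5 (0.9800). The first principal component held 54.5% of the variance and parted the groups, with hCG 6 nearest to the controls. The second held 21.6% and set Control 7 (0.88) apart from the other 5 arrays (-0.38 to -0.06).

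Bacterial poly-A transcripts, which are added to the RNA before labelling, were lower on all 3 hCG arrays. Their mean log2 level was 6.55 ± 0.14 (SD, n = 3) on control arrays and 5.65 ± 0.33 (SD, n = 3) on hCG arrays, a 1.88-fold difference (exact permutation test, two-sided p = 0.1, the smallest possible). On hCG 6 the level was 6.02. Transcripts added at hybridisation differed by -0.22 (7.57 ± 0.10 against 7.35 ± 0.11; exact permutation, two-sided p = 0.1). The 3' minus 5' signal of Actb, a measure of RNA integrity, was 1.76 ± 0.37 on control arrays and 1.63 ± 0.11 on hCG arrays (exact permutation, two-sided p = 0.8). Control 7 had the highest value, 2.18. For Gapdh the means were 0.33 ± 0.30 and 0.11 ± 0.06 (exact permutation, two-sided p = 0.3). The lower spike level on hCG arrays accompanied every gene group described here.

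Endothelial genes were higher in hCG spheres by limma's camera test with a preset correlation of 0.01 (adjusted p = 1.43e-05), and not with an estimated one (adjusted p = 0.474 with an estimated correlation). Of 13 measured markers 12 lay above 0, with a median log2 change of 0.97, and 3 rose over all genes: Sox17, the endothelial glycoprotein gene Emcn and the junction gene Esam (0.98, SE 0.14). Adjusted over the list alone, 11 rose. Erg, a transcription factor of endothelial cells, had a change of 0.62 (SE 0.11, limma adjusted p = 0.0513). The mean marker level, relative to the control mean, was -0.30, -0.18 and 0.47 on control arrays and 1.00, 1.02 and 0.94 on hCG arrays. Without Control 7, the control array of highest marker level, 10 of the 13 markers passed the gene test. Without hCG 6, Emcn and Esam lost their call, and without Control 5, Control 6, hCG 5 or hCG 7 limma called 0 genes. The same 0 calls limit the counts without Control 7 given below for other lists.

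Fibroblast and matrix genes rose as a list by a smaller amount, with a median of 0.32 over 22 genes (camera adjusted p = 0.00513; adjusted p = 0.474 with an estimated correlation). Over all genes 1 rose and 1 fell; adjusted over the list alone 9 rose and 1 fell. Lum, a collagen-binding proteoglycan, rose by 1.13 (SE 0.17), while Dpt, another matrix protein, fell by 0.99 (SE 0.15). The collagen genes Col3a1 and Col6a3 had changes of 0.37 and 0.50 (limma adjusted p = 0.0620 and 0.0633), and Postn of 0.43 (adjusted p = 0.104). Without Control 7, 6 genes of the list were called higher and 1 lower. Mean levels of the list overlapped between the groups, with 0.21 on Control 7 and 0.17 on hCG 6 (exact permutation, two-sided p = 0.2). Other non-epithelial cell types did not pass camera. Medians were -0.15 for 9 macrophage markers (camera adjusted p = 0.462), 0.13 for 8 pericyte markers (0.462), 0.02 for 8 adipocyte markers (0.630), -0.10 for 7 Schwann cell markers (0.630) and 0.19 for 10 skeletal muscle markers (0.893). In these lists the pericyte gene Rgs5 (0.66, SE 0.11) and Fabp4, which capillary endothelium also expresses, rose. Limma's fry test for change in either direction passed for macrophage (adjusted p = 0.00326), pericyte (0.00364) and adipocyte markers (0.00288). Lymphocyte, mast cell and granulocyte, and erythroid markers had 3, 4 and 1 measured genes, too few to test.

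Mitosis genes were higher in hCG spheres by camera (adjusted p = 9.15e-08; adjusted p = 0.474 with an estimated correlation). All 23 measured genes lay above 0, with a median log2 change of 0.73. Over all genes 2 rose, Cdk1, the kinase that drives entry into mitosis (1.53, SE 0.26, limma adjusted p = 0.0466), and the kinetochore gene Cenpf (0.86, SE 0.14, adjusted p = 0.0447). Adjusted over the list alone, 19 rose. Ccna2, Cks2 and the proliferation marker Mki67 had changes of 1.22, 0.69 and 0.88 (adjusted p = 0.0618, 0.0595 and 0.136). Mean levels of the list were -0.08, -0.02 and 0.11 on control arrays and 1.05, 0.29 and 0.84 on hCG arrays, the lowest being hCG 6, whose spike level was nearest to the controls.

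S phase and replication genes rose with a median of 0.46 over 21 genes (camera adjusted p = 3.09e-05; adjusted p = 0.474 with an estimated correlation). Over all genes 2 rose, the primase subunit Prim1 (0.73, SE 0.11) and the DNA polymerase subunit Pola1 (0.53, SE 0.09); adjusted over the list alone, 8 rose. Pola1 missed the threshold when dim probe sets were kept (adjusted p = 0.0504). The helicase genes Mcm4 and Mcm6 had changes of 0.62 and 0.74 (limma adjusted p = 0.0629 and 0.0763). The median of the list was 0.29 without hCG 5 and 0.23 with the dimmest 60% of probe sets left out. Ribosomal protein genes rose as a list by little, with a median of 0.19 over 15 genes, all above 0. None passed over all genes or adjusted over the list alone (camera adjusted p = 0.000475; adjusted p = 0.556 with an estimated correlation). Rps3 had the smallest p of the list, at a change of 0.26 (limma adjusted p = 0.127), followed by Rpl7 (0.23), Rps24 (0.25) and Rpl14 (0.21).

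**Figure D2:**
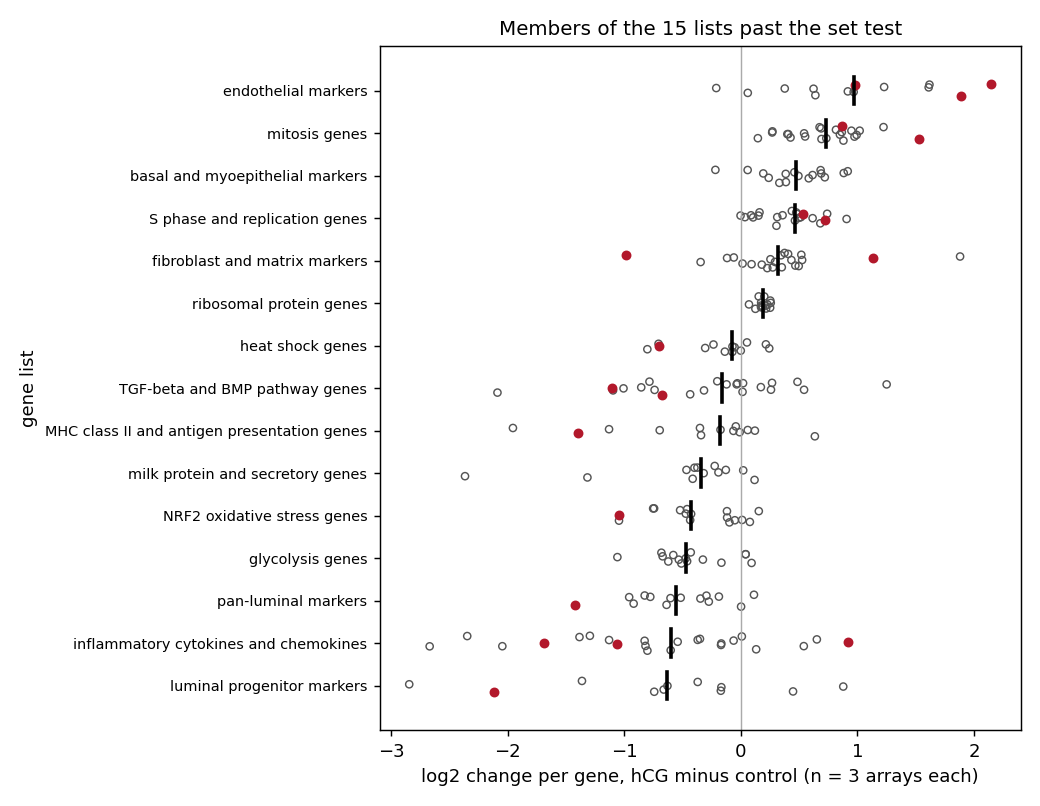
Log2 change per gene, hCG minus control (horizontal axis, n = 3 arrays per group), of the members of the 15 gene lists that passed camera with a preset correlation (rows). Filled points passed the gene test at adjusted p under 0.05, open points did not, and black bars are medians, from -0.63 for luminal progenitor markers to 0.97 for endothelial markers.

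By camera with a preset correlation, pan-luminal markers were lower (adjusted p = 0.00279) and basal and myoepithelial markers higher (adjusted p = 0.0155). Neither call held, each at an adjusted p = 0.615 with an estimated correlation, and levels of both lists overlapped between the groups (exact permutation, two-sided p = 0.4 and 0.2). Pan-luminal markers had a median of -0.56 over 14 genes, of which 1 fell both over all genes and adjusted over the list alone: Cd24, a surface glycoprotein of luminal cells (-1.42, SE 0.15, limma adjusted p = 0.0329). The claudins Cldn7 and Cldn3 and the transcription factor Elf3 had changes of -0.92, -0.78 and -0.35 (adjusted p = 0.259, 0.263 and 0.236). The luminal keratins Krt8 and Krt18 had changes of 0.11 (SE 0.38) and -0.19 (SE 0.42). Basal and myoepithelial markers had a median of 0.48 over 16 genes, with 0 called over all genes and 0 adjusted over the list alone. The basal keratins Krt14 and Krt5 had changes of 0.92 (SE 0.45, adjusted p = 0.284) and 0.69 (SE 0.43, adjusted p = 0.395), the integrin Itga6 of 0.88 (SE 0.28, adjusted p = 0.132), Myh11 of 0.58 (adjusted p = 0.0994) and Acta2 of 0.38 (adjusted p = 0.177). Without Control 5 the changes of Krt14, Krt5 and Itga6 were 0.44, 0.26 and 0.58, and that of Cldn7 was -1.42, while without Control 7 those of Cldn7 and Cldn3 were -0.54 and -0.42. With 1 array left out in turn, Krt8 lay between -0.34 (without Control 5) and 0.49 (without Control 7), and Krt18 between -0.63 (without Control 5) and 0.29 (without Control 7). Krt5 was 1.05 without hCG 5. Without Control 7, 2 basal genes passed over all genes, Myh11 (0.72, adjusted p = 0.0470) and Tagln (1.02, adjusted p = 0.0438), both contractile cell genes.

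Both lists varied widely among control arrays. Mean pan-luminal levels were -0.79, 0.14 and 0.65 on control arrays and -0.37, -0.57 and -0.70 on hCG arrays; basal levels were -0.59, 0.09 and 0.49 on control arrays and 0.32, 0.52 and 0.56 on hCG arrays. The luminal minus basal difference did not overlap, at 0.00 ± 0.18 (SD, n = 3) and -1.01 ± 0.29 (exact permutation, two-sided p = 0.1, the smallest possible), while the mean of both levels was 0.00 ± 0.64 and -0.04 ± 0.02 (exact permutation, two-sided p = 1). Without Control 7 the luminal median was -0.20 and its call was lost (adjusted p = 0.105), while without Control 5 it was -0.98. Without Control 5 the basal median was 0.23 and its call was lost (adjusted p = 0.182), while without Control 7 it was 0.76, and the basal call was also lost with the dimmest 60% of probe sets left out (0.68, adjusted p = 0.0854).

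Luminal progenitor markers fell with a median of -0.63 over 11 genes (camera adjusted p = 0.00362; adjusted p = 0.474 with an estimated correlation), and 1 fell both over all genes and adjusted over the list alone, the lipopolysaccharide-binding protein gene Lbp (-2.12, SE 0.22, limma adjusted p = 0.0329). Csn3, the kappa-casein gene, had a change of -2.84 with an SE of 0.96 (adjusted p = 0.152). Lcn2, an iron-trapping defence protein, had one of -1.36 and Cd14 one of -0.66 (adjusted p = 0.15 and 0.131). The median of the list was -0.41 without hCG 5 and -0.38 with no filter on dim probe sets. Its mean levels overlapped between the groups, with -0.48 on Control 5 and -0.44 on hCG 5 (exact permutation, two-sided p = 0.2). Milk protein and secretory genes fell with a median of -0.35 over 12 genes (camera adjusted p = 0.00104; adjusted p = 0.474 with an estimated correlation). Over all genes 0 fell, and adjusted over the list alone 2 fell. The lipid droplet gene Plin2 had a change of -0.37 (SE 0.08, adjusted p = 0.0595), Xdh of -0.41 (adjusted p = 0.0908), Spp1 of -0.32 (adjusted p = 0.170) and the casein gene Csn1s1 of -2.37 (SE 0.78, adjusted p = 0.144). The median of the milk list was -0.23 without Control 7 and -0.21 with no filter. Mean levels of the milk list also overlapped, with -0.22 on Control 5 and -0.14 on hCG 5 (exact permutation, two-sided p = 0.2).

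**Figure D3:**
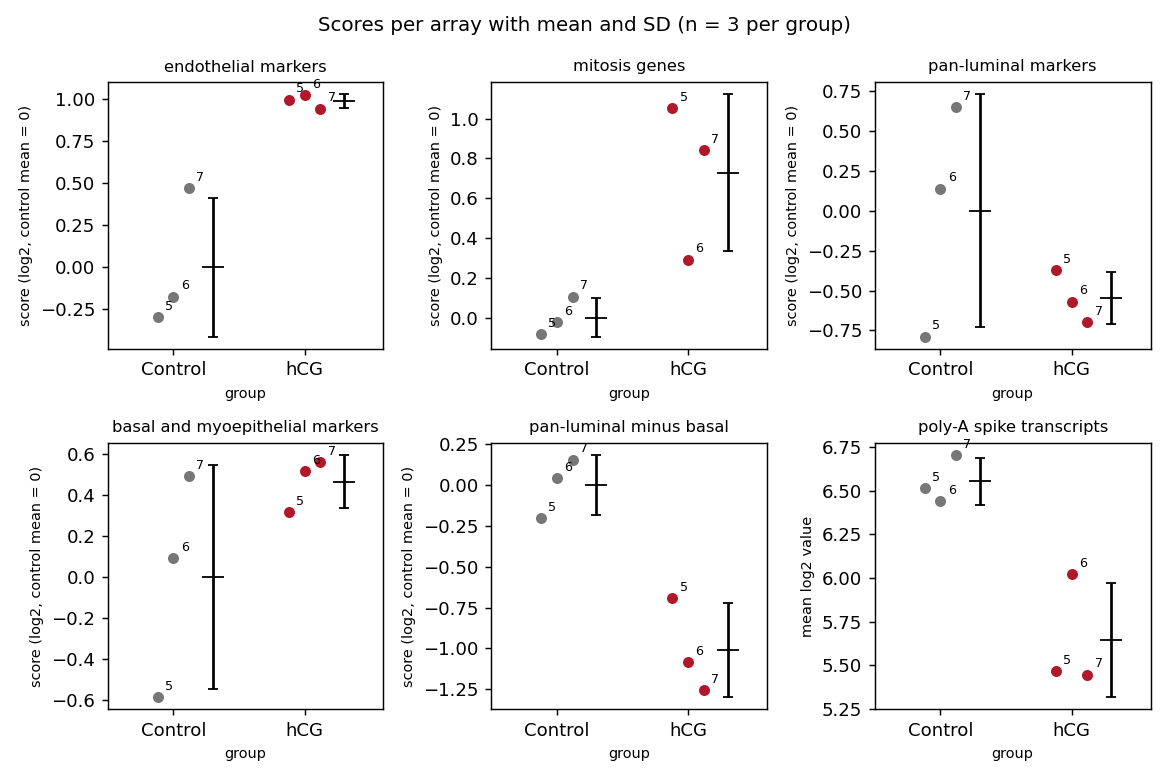
Mean level per array of 4 gene lists, the pan-luminal minus basal difference (all in log2, control mean 0) and the mean log2 level of the poly-A spike transcripts, with the array number beside each point and the group mean and SD at the side (n = 3). Luminal and basal levels overlapped between groups, while their difference (-1.01 on average on hCG arrays) and the spike level (6.55 and 5.65) did not.

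Hormone-sensing luminal markers did not pass as a list (median -0.15 over 8 genes, camera adjusted p = 0.224), with 1 higher (Ptn) and 1 lower (Fxyd2) over all genes. Mammary stem cell associated genes had a median of 0.02 and a mean of -0.15 over 13 genes (camera adjusted p = 0.630). Of the surface markers used to sort mammary cells, Cd44 had a change of -0.78 (SE 0.22, limma adjusted p = 0.110) and Itgb1 of 0.09 (SE 0.08, adjusted p = 0.559). The receptor gene Notch1 had a change of 0.71 (SE 0.13, adjusted p = 0.0513), and passed without Control 7 (0.80, adjusted p = 0.0365) and without hCG 6 (0.81, adjusted p = 0.0495). The gonadotropin receptor gene Lhcgr was among the dimmest 40% of probe sets, at 1.47 ± 0.06 (SD, n = 3) on control arrays and 1.25 ± 0.14 on hCG arrays (limma adjusted p = 0.297 without the filter). Esr1, Pgr, Prlr, Csn2, Elf5, Kit, Aldh1a1 and Inha were also below the filter, with means from 1.32 to 2.83 and adjusted p from 0.325 to 0.924 when tested without it.

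Lists of sugar breakdown and oxidative defence genes passed camera as lower in hCG spheres (adjusted p = 5.47e-05 for glycolysis and 0.000249 for NRF2 genes), and neither did with an estimated correlation (adjusted p = 0.474 with an estimated correlation for each). Glycolysis genes had a median of -0.47 over 15 genes, of which 0 fell over all genes and 7 adjusted over the list alone. The hexokinase gene Hk1 had a change of -0.68 (SE 0.14, limma adjusted p = 0.0580), Gpi of -0.53 (adjusted p = 0.0766), Eno2 of -0.47 (adjusted p = 0.0871) and Eno1 of -0.51 (adjusted p = 0.0896). NRF2 oxidative stress genes had a median of -0.43 over 16 genes. Over all genes 1 fell, the quinone reductase gene Nqo1 (-1.04, SE 0.16, adjusted p = 0.0432), and 5 adjusted over the list alone. Taldo1, Me1 and Gsta1 had changes of -0.46, -0.43 and -0.52 (adjusted p = 0.0557, 0.0689 and 0.0869). Without Control 7, 3 genes of the list fell over all genes: Nqo1, Taldo1 (-0.49, adjusted p = 0.0451) and the heme oxygenase gene Hmox1 (-1.02, adjusted p = 0.0368).

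Heat shock genes passed camera at the margin, with a median of -0.07 and a mean of -0.20 over 13 genes (adjusted p = 0.0360; adjusted p = 0.474 with an estimated correlation). The chaperone gene Hsph1 fell over all genes (-0.71, SE 0.12, limma adjusted p = 0.0470), and 2 fell adjusted over the list alone. Hsph1 missed the threshold when its probe sets were averaged (adjusted p = 0.0687). Chordc1, Hspa1a and Bag3 had changes of -0.31, -0.80 and -0.23 (adjusted p = 0.0799, 0.125 and 0.166). The list call was lost without Control 6 (-0.10, camera adjusted p = 0.0796), Control 7 (-0.07, 0.0526) or hCG 6 (-0.13, 0.0821), and without Control 5 the median was -0.14 (0.0345). It was -0.11 with cyclic loess and -0.13 with the mean of a gene's probe sets.

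Inflammatory cytokine and chemokine genes fell as a list, with a median of -0.60 over 23 genes (camera adjusted p = 0.000304; adjusted p = 0.474 with an estimated correlation). Over all genes 2 fell, Csf3 (-1.69, SE 0.18, limma adjusted p = 0.0329) and the interleukin gene Il1a (-1.06, SE 0.17, adjusted p = 0.0432), while Tnf rose (0.92, SE 0.15, adjusted p = 0.0465). The hCG mean of Il1a, 2.64, lay below the filter level of 2.67. Adjusted over the list alone 5 fell and 2 rose. The chemokine gene Ccl20 and the acute phase gene Saa3 had changes of -2.35 (SE 0.62) and -2.67 (SE 0.71; adjusted p = 0.0948 and 0.0964). Without Control 5 the median of the list was -0.40. Without Control 7, Lif also fell (-1.79, adjusted p = 0.0446).

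Antigen presentation genes fell with a median of -0.17 and a mean of -0.41 over 13 genes (camera adjusted p = 0.00513; adjusted p = 0.474 with an estimated correlation). Over all genes 1 fell, the MHC class II gene RT1-Da (-1.39, SE 0.18, limma adjusted p = 0.0393), and 4 adjusted over the list alone. The class II gene RT1-Db1 and the class II chaperone gene Cd74 had changes of -1.13 and -1.95 (adjusted p = 0.0580 and 0.0593), and the peptide transporter gene Tap1 one of -0.35 (adjusted p = 0.120). Cd74 passed without hCG 6 (-2.35, adjusted p = 0.0361). The median of the list was -0.35 with the dimmest 60% of probe sets left out and -0.34 with the mean of a gene's probe sets.

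TGF-beta and BMP pathway genes fell with a median of -0.16 and a mean of -0.29 over 22 genes (camera adjusted p = 0.0360; adjusted p = 0.497 with an estimated correlation). Over all genes 2 fell, the BMP target Id1 (-0.68, SE 0.09, limma adjusted p = 0.0393) and Ltbp2, a matrix protein of elastic fibres (-1.10, SE 0.16, adjusted p = 0.0405). Adjusted over the list alone 4 fell and 3 rose. The ligand gene Bmp2 had a change of -2.09 (SE 0.40, adjusted p = 0.0557), and passed without Control 7 (-2.55, adjusted p = 0.0165), with a variance trend (adjusted p = 0.0474) and with the mean of its probe sets (-2.37, adjusted p = 0.0360). Its dimmer probe set changed by -2.65 (adjusted p = 0.0393). Without Control 7, 3 genes of the list fell (Id1, Ltbp2 and Bmp2) and 2 rose, Tgfbi (1.46, adjusted p = 0.0407) and Smad3 (0.69, adjusted p = 0.0348). The inhibitor gene Smad7 had one of -0.74 (adjusted p = 0.101). The list call was lost without Control 6 (-0.14, camera adjusted p = 0.179), without hCG 5 (-0.09, 0.0696), with cyclic loess (-0.17, 0.0563) and with the dimmest 60% of probe sets left out (-0.32, 0.0847). Without Control 5 the median was -0.26, without hCG 6 it was -0.25, and with no filter it was -0.10. Of the inhibin and gonadotropin genes, 1 rose and 1 fell over all genes: the growth hormone receptor gene Ghr rose (0.88, SE 0.09, adjusted p = 0.0329) and the activin subunit gene Inhbb fell (-1.40, SE 0.21, adjusted p = 0.0417). Inhba had a change of -0.62 (SE 0.20, adjusted p = 0.137). That list did not pass (median -0.09 over 10 genes, camera adjusted p = 0.638).

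Of 42 tested lists, 15 passed camera with the preset correlation, 6 higher and 9 lower. With an estimated correlation 0 passed (0 at an unadjusted p under 0.05), and limma's fry, which asks whether a list's genes move on balance one way, passed 0 (smallest adjusted p 0.0723, 18 at an unadjusted p under 0.05). Its mixed test, which asks whether genes change in either direction, passed 34 lists. The lists nearest to the camera threshold were splicing factors (median 0.10, adjusted p = 0.0721), oxidative phosphorylation (0.11, 0.0768) and matrix metalloproteinases and inhibitors (-0.16, 0.0955). In the last, Plau, the urokinase gene, rose by 1.10 (SE 0.17, limma adjusted p = 0.0432). Wnt pathway genes had a median of 0.03 and a mean of -0.13 (adjusted p = 0.241), with the secreted Wnt modulator Sfrp4 higher by 1.64 (SE 0.21, adjusted p = 0.0393). Adjusted p was 0.104 for fatty acid synthesis and for the unfolded protein response, 0.120 for hypoxia, 0.155 for mesenchymal transition, 0.224 for apoptosis, 0.331 for interferon response and 0.367 for immediate early genes. It was 0.377 for complement and for Notch, 0.462 for EGF and FGF response, 0.525 for p53 targets, 0.529 for cholesterol synthesis, 0.742 for chromatin regulators, 0.839 for circadian clock and 0.980 for cornified epithelium genes. Camera's direction was lower while the median lay above 0 for the Wnt, interferon (0.02), stem cell (0.02) and cornified epithelium (0.06) lists, and the mean differed in sign from the median for the interferon, circadian clock, Schwann cell, Wnt and stem cell lists.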

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

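All alternatives but 1 were chosen before the data were examined; the threshold of adjusted p under 0.10 was chosen after the result was seen. The sign of the median of the 15 called lists held in each alternative run for them (with shared genes left out, luminal progenitor markers were not tested, and the trend, robust and minimum fold settings were run on genes only), while the number of genes called depended strongly on the arrays and the variance model. Against 177 genes and 298 probe sets, leaving out 1 array gave 0 to 587 genes and 0 to 1064 probe sets: 0 genes by limma without Control 5, Control 6, hCG 5 or hCG 7 (1950, 1931, 1649 and 1455 at an unadjusted p under 0.05), 587 without Control 7 and 245 without hCG 6 (173 and 112 of them among the 177). Fewer arrays leave fewer degrees of freedom. With the array number as a replicate block limma called 0 genes and 1 probe set (2205 and 3821 at an unadjusted p under 0.05), with 15 lists called as before. Same-numbered arrays' deviations from their group means correlated at -0.09, 0.13 and 0.00 for numbers 5, 6 and 7. By these deviations Control 6 and hCG 6 matched each other best, while the arrays numbered 5 and 7 matched best with another number. So few arrays cannot decide whether the numbers mark a shared litter, day or batch, and the block result is not set aside. Array weights, which gave hCG 7 a weight of 7.25 and Control 7 one of 0.23, called 2540 genes and 4253 probe sets. eBayes with trend called 293 and 500, a log2 fold of at least 1 left 70 and 103, and adjusted p under 0.10 gave 829 and 1456; the cause of the rise with trend was not tested. The other settings of filter, normalization, robustness and probe set averaging called 164 to 253 genes. Lists past camera numbered 14 to 16 with 1 array left out and 13 to 17 with other settings. With an estimated correlation 0 passed and with fry 0, which allow for the correlation of the genes. Correlation alone does not account for this loss: heat shock (estimated correlation -0.03) and antigen presentation genes (0.05) were lost too. Of 87 named genes, 2 changed sign. Krt18, at -0.19, was 0.01 with array weights (0.00556 unrounded) and -0.63 to 0.29 with 1 array left out, turning without Control 7; Krt8, at 0.11, was -0.34 to 0.49, turning without Control 5. Neither was called in any of these. Array weights aside, Bmp2, Ccna2, Cd44, Cd74, Cks2, Col3a1, Col6a3, Erg, Hk1, Myh11, Notch1, Plin2 and Taldo1 passed under at least 1 other setting. The difference between within- and between-group correlation, 0.0114, was 0.00490 with no filter and 0.0183 with the 60% filter; the cause was not tested. Genes below the filter, the receptors Lhcgr, Esr1 and Pgr among them, are limited by dim signal, and how near it lay to background was not measured.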

Other observations

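The tests on the epithelial share (on levels per array, since exchanging genes between lists would treat correlated genes as independent), on dilution and on the spiked transcripts were chosen only after the results were seen, and the genes in the next paragraphs were chosen after their values were seen, beyond those the naming rule gave. Other genes known from endothelial cells, picked singly, were among those called by limma. Lyve1, a receptor of lymphatic endothelium and some macrophages, rose by 1.72 (SE 0.28), Rasgrp3 by 1.67 (SE 0.26), Icam2 by 1.66 (SE 0.23), Sox18 by 1.37 (SE 0.20) and the angiopoietin gene Angpt2 by 1.28 (SE 0.15), with limma adjusted p between 0.0350 and 0.0453. Cyp1a1 and Cyp1b1, which encode enzymes that oxidise foreign compounds and were not tested as a group, fell by 0.98 (SE 0.17) and 1.06 (SE 0.16; adjusted p = 0.0487 and 0.0405).

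Some genes of growth signalling and the cell cycle, picked singly and not tested as a group, were also called. The EGF receptor gene Egfr (0.68, SE 0.11) and its feedback inhibitor Errfi1 (0.74, SE 0.09) rose and Fgfr1 fell (-0.65, SE 0.09), with limma adjusted p = 0.0466, 0.0393 and 0.0393, while their list did not pass camera (median -0.10, adjusted p = 0.462). Myc rose by 0.86 (SE 0.13), whereas the cyclin gene Ccnd1 fell by 0.84 (SE 0.09) and Cdkn2a, an inhibitor of the cell cycle, by 1.34 (SE 0.20; adjusted p = 0.0405, 0.0329 and 0.0405). As with all gene calls here, none of these passed without Control 5, Control 6, hCG 5 or hCG 7, where limma called 0 genes.

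For the count of called probe sets, the 6 arrays have too few splits for a share under 0.05. The real grouping gave 298 and the highest of the other splits gave 0, so that 1 of 10 splits gave as many.

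Endothelial markers were higher in all 3 hCG arrays. A lower epithelial share could raise all other cell types alike. Endothelial levels rose above the mean of 6 other non-epithelial lists by 0.794 (95% interval 0.09 to 1.5 on 4 degrees of freedom). Singly the interval lay above 0 for the fibroblast (0.68, 0.23 to 1.13), pericyte and Schwann cell lists. It held 0 for the macrophage (1.00, -0.04 to 2.04), adipocyte and skeletal muscle lists. The endothelial list was chosen because it had risen most, which the intervals do not allow for, so they cannot decide this. More endothelial RNA in the hCG spheres is a candidate explanation. The 17 endothelial genes tested outside the list had a median change of 0.59, with 14 above 0. Their bootstrap interval, 0.14 to 0.95, resampled genes as if independent, so it does not measure the spread between arrays. None was called alone, and camera with an estimated correlation gave p = 0.172. More endothelial RNA may reflect endothelial cells carried through the epithelial enrichment and the sphere culture, or endothelial genes switched on in other cells. These data do not separate the 2. The spiked transcripts stay open for want of precision: the within-group slope on the spike level was 0.49, opposite in sign to what they would need, which raised the difference from 0.99 to 1.43, but with a 95% interval of -0.52 to 3.38 on 3 degrees of freedom.

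Luminal markers were lower and basal markers higher, though each list's level overlapped between the groups. Dilution of all epithelial RNA would lower both alike and leave their difference on an array near 0 only if the diluting cells expressed neither list. This was not measured, and the basal list holds contractile cell genes such as Acta2, Myh11 and Tagln, which need not come from epithelium. The difference fell by 1.01 (95% interval -1.56 to -0.46 on 4 degrees of freedom). These lists were chosen after their directions were seen, which the interval does not allow for, so it cannot settle whether dilution was the whole cause. A change in the share of luminal and basal cells may account for the lower difference. Further luminal genes had a median of -0.16 (7 genes) and further basal genes one of 0.11 (14 genes), too small to decide. The within-group slope on the spike level was -0.04, also opposite in sign to that needed, and after it the luminal minus basal difference was -1.05 with a 95% interval of -2.82 to 0.72, so that the amount of RNA stays open too. Without Control 7 the luminal median was -0.20 and without Control 5 the basal median was 0.23, and neither list then passed.

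Cell division genes were higher in hCG spheres, by a median of 0.73 for mitosis genes. A single array as the source is argued against, since the median lay between 0.59 and 0.98 whichever array was left out. The spiked transcripts stay open: the pooled slope within groups was -0.89 per log2 unit of spike level, and the difference left after it was -0.0815, with a 95% interval of -1.38 to 1.21 that holds both 0 and the whole 0.73. If each sample received the same amount of spike, less spike signal means more sample RNA in the reaction, and more dividing cells may also yield more RNA, so that cause and consequence cannot be told apart for these genes. An effect of the hCG treatment on growth in culture remains an open hypothesis.

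RNA degradation was weighed for these 3 patterns together. The 3' minus 5' value of Actb differed by -0.13 between the groups and overlapped, as did that of Gapdh (-0.22). Overlap had been set beforehand to count against degradation, but the 95% interval of the Actb difference, -0.76 to 0.49, is too wide for that with 3 arrays per group, and degradation cannot be told apart for any of the 3. The spiked transcripts' own 3' minus 5' value was 1.58 ± 0.25 on control arrays and 1.96 ± 0.14 on hCG arrays (exact permutation, two-sided p = 0.1, the smallest possible), a sign that labelling may have differed.

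Other hypotheses gave no clear answer. Mest, the second largest rise, is imprinted, and 14 other imprinted genes had a median change of 0.24. The bootstrap interval over genes, taken as independent, was -0.01 to 0.50. Of these genes 10 lay above 0, with Grb10 at 1.02, Meg3 at 0.80 and Cdkn1c at 0.79, and 4 lay below 0. Of the 14 genes, 0 were called. Camera of limma gave the list an unadjusted p of 0.05, and of 0.106 with an estimated correlation. The rule set beforehand asked for a larger median together with a camera p under 0.05, and was not met. A camera p at or above 0.05 was to count against a shared rise, and the p of 0.05 lay at that limit. A shared rise is therefore not established. Cd83, which falls outside the naming rule, fell by 1.28 (SE 0.11), as did RT1-Da and Cst7, which suggested fewer dendritic cells. Of 9 further dendritic cell genes the median was -0.0063 (bootstrap interval over genes, taken as independent, -0.996 to 0.416). Cd86 fell (-0.81, limma adjusted p = 0.0432), Ccl17 and Ccl22 lay at -1.24 and -0.996, and Itgae and Batf3 at 0.43 and 0.42. By the rule set beforehand, this median and the camera p of 0.18 counted against fewer dendritic cells. The members split in direction, so the list as a whole decides nothing.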
